A study of Mus musculus with 77 samples.

How the data were processed

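RNA of male mice aged 12 weeks on HFD or LFD for 2 weeks was sequenced as 77 libraries: liver and kidney mRNA and liver, VsWAT, GAS and plasma small RNA as input and pull-down, and VsWAT and GAS total RNA as input. Per the labels, plasma was spin-filtered and extracted with Tri reagent BD, tissues were extracted with NucleoZOL, and libraries were made with a CATS small RNA kit and read single-end at 75 bp. The deposited files hold raw counts per gene, made by the authors with STAR and HTSeq on mm10 according to their processing notes, which give no versions. The mRNA and small RNA files list 55273 features, of which 435 are tRNA loci, and the total RNA files 55421 with 5 further summary lines per library. In total RNA, reads without a unique alignment came to 11.84% to 21.32% of the reads listed and reads in no feature to 19.58% to 32.31%. Whole numbers, differing totals and labels were checked against this reading of the unit, and replicates were grouped by tissue, RNA type, fraction and diet as the labels state.

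Assigned counts per library ranged from 3033702 to 4942158 in liver mRNA input, 3389320 to 4426392 in its pull-down, 7970076 to 19645443 in kidney mRNA input, 3741335 to 13713002 in its pull-down, 875970 to 3608065 and 573697 to 3338652 in liver small RNA (input first), 881578 to 2220123 and 1867345 to 2580104 in VsWAT small RNA, 849006 to 2315092 and 1643420 to 2486106 in GAS small RNA, 327144 to 828030 and 221875 to 646964 in plasma, 3218698 to 9528377 in VsWAT total RNA and 4894520 to 9749492 in GAS total RNA. A count of 0 in a group was read as below a floor of 3 counts over its libraries, folds against it are given as at least that size, and groups with 1 to 3 counts get no fold. These floors cover counting error alone, not the spread between animals.

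Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM scaling, filterByExpr with a minimum of 10 counts) in R 4.3.3, 2-sided, with a Benjamini-Hochberg adjusted p under 0.05 and no fold limit, and SE is the absolute log2 fold change over the square root of F. The 30 comparisons are pull-down against input in 6 sets over both diets, HFD against LFD within each of 14 sets of libraries, the diet by pull-down interaction in 6 sets and 4 differences between tissues. Means of named genes are CPM after TMM scaling, and CPM of all assigned counts are used where the text says so. Fixed before the data were examined were the comparisons, tests, alternatives, the rule for named genes and 39 gene lists. The rule takes, of called genes with a mean of at least 20 counts, a full gene symbol and no overlap between the sides' libraries (not asked of differences between comparisons), the 8 largest changes each way in the main comparisons and 4 each way in others, or the 3 smallest p where none passed, stopping earlier in the ranked list where space asks for it. It adds up to 4 list members with the smallest p, the Cyp3a genes, Alb and Mir122. Main comparisons are pull-down against input in liver mRNA and VsWAT small RNA, the liver minus kidney difference, and diet in liver mRNA input, VsWAT total RNA and GAS total RNA.

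Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Of 703 list tests 241 were called with the preset correlation, 15 with an estimated one and 138 by fry. The 84 list tests over 22 lists that the text describes were picked after these results were seen. Shares of counts per RNA class were compared by exact permutation of libraries, and calls shared between tissues are set against the number that independent lists would share. Mir122 is left out of the liver minus kidney differences, since kidney holds 0 counts of it.

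Alternatives were DESeq2 1.42.0, DESeq2-type size factors, total-count scaling, no filter on low counts, a dispersion from all 4 groups, the replicate number as a block and leaving out each library. Added after the data were seen were the summing of near-identical libraries (chi-square per degree of freedom under 2, where 70 pairs ranged from 1.153 to 175.547), and runs without kidney inputs with over 15% of mitochondrial mRNA, total RNA libraries with over 3% of Gm42418 and VsWAT small RNA replicates with over 300 CPM of Alb in input, and crossed numbers in plasma input. Where a group is left with 1 library it is assumed to vary like the others. Replicate numbers were taken to pair libraries where, with 3 pairs or more, deviations from group means correlated over 0.1 in every pair, over genes with at least 20 counts: liver mRNA pull-down between diets (0.16 to 0.181), GAS small RNA input with pull-down (0.434 to 0.647), and total RNA with small RNA input in VsWAT (0.347 to 0.548) and GAS (0.281 to 0.798). Plasma inputs of the 2 diets correlated at -0.548.

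The tests were tested on simulated data with 200 changed genes. Of genes changed 2-fold and 4-fold, 91% and 100% were called with the spread of liver mRNA pull-down against input, 70.1% and 100% in VsWAT small RNA, 47.8% and 92.4% for liver minus kidney, 22.4% and 87.9% for diet in liver mRNA input, 62.7% and 93.9% in VsWAT total RNA, 17.9% and 77.3% in GAS total RNA, and 0% and 0% in plasma for pull-down and for diet in pull-down. Unchanged genes made up from 8 of 156 calls in the first of these to 11 of 84 for diet in liver mRNA input and 10 of 74 in GAS total RNA. In these plasma tests a change of 4-fold was thus not detectable, and the part of depth and of the spread between replicates in this was not tested. Results for items withheld for evaluation are not reported here. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.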

Results

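The RNA came from male mice aged 12 weeks that had eaten a high-fat diet (HFD) or a low-fat control diet (LFD) for 2 weeks. Their strain carries a targeted Cyp3a13 gene, a deletion spanning Cyp3a57 to Cyp3a59 and a human CYP3A4 transgene driven by APOE sequences. Labelled RNA was pulled down from part of the material, and its libraries are set against the input libraries of the same tissue. Libraries were of liver and kidney mRNA, liver, VsWAT, GAS and plasma small RNA, and VsWAT and GAS total RNA (input alone). VsWAT and GAS are the labels' own names, and neither the label compound nor the pull-down protocol is named. The 77 libraries formed 28 groups, 21 of 3 and 7 of 2, and whether each replicate was a separate animal is not stated. Fold changes are log2 values ± SE from edgeR, levels are mean ± SD in CPM (read counts scaled per library) after TMM scaling unless stated, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Rankings by size of change cover only genes that passed, met the naming rule and had counts enough for a fold. For a gene list, brackets give its calls adjusted over the list alone, the adjusted p of camera (camera q) and that with an estimated correlation (est. q).

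Some libraries stood apart in gene content. Liver mRNA input LFD 1 held 158 CPM of Kap, an androgen-regulated kidney protein gene, where the other 5 liver inputs held 7.87 to 41.2 CPM of all assigned counts. Mitochondrially encoded mRNAs made up 16.6% of kidney input HFD 1 and 17.6% of LFD 1, against 11.6% to 12.0% in the other kidney inputs. Alb, the serum albumin gene, reached 642, 894 and 1063 CPM in VsWAT small RNA inputs HFD 1, HFD 2 and LFD 1 and 108 to 262 CPM in the other inputs. The transcript Gm42418 took 7.51%, 7.11% and 3.63% of VsWAT total RNA HFD 3, LFD 1 and LFD 3 and 6.15% of GAS total RNA HFD 1, against 0.046% to 1.17% in the other total RNA libraries. In 3 pairs of libraries the counts differed by little more than counting error, with a chi-square per degree of freedom of 1.224 for liver mRNA inputs HFD 1 and 3, 1.153 for LFD 2 and 3 and 1.857 for VsWAT small RNA inputs HFD 1 and 2. They were kept as separate replicates (n = 3), and a count with each pair summed is given where it differs.

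Cyp3a13 (ENSMUSG00000029727), a cytochrome P450 gene that the strain name lists as targeted, had counts in every liver group. In CPM of all assigned counts it reached 119 ± 38.1 in liver mRNA input on HFD (n = 3) and 58.8 ± 46.2 on LFD (n = 3), and 131 ± 22.1 and 77.7 ± 13.7 in the pull-downs (n = 3 each). Within the LFD inputs, LFD 1 held 17 counts of Cyp3a13, 5 of Cyp3a16 and 0 of Cyp3a11, which allows up to 0.989 CPM, while LFD 2 and 3 held 352 and 334 counts of Cyp3a13. Kidney mRNA held 0.932 ± 0.692 CPM of Cyp3a13 in HFD input (n = 3) and 5.58 ± 2.03 in LFD input (n = 2), with 10.1 ± 3.47 and 6.85 ± 2.48 in the pull-downs (n = 3 and n = 2). Cyp3a57 ranged from 4.16 to 9.15 CPM and Cyp3a59 from 5.87 to 35.1 CPM over the liver mRNA groups, although both lie at the ends of the deletion named in the strain. Over all comparisons of diet the Cyp3a calls were 0.62 ± 0.14 for Cyp3a13 and 1.13 ± 0.20 for Cyp3a59 in liver mRNA pull-down. Cyp3a genes share sequence with each other and with CYP3A4, and no library of another genotype was analysed here, so these counts do not test the genotype.

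Tat, the tyrosine aminotransferase gene of hepatocytes, was higher in liver mRNA pull-down than in input, at 20690 ± 5222 against 4289 ± 1386 CPM (n = 6 each, 2.31 ± 0.12). Ahead of it among genes ranked by that rule were 2.93 ± 0.37 for Snord49a, 2.77 ± 0.29 for Sycp1, 2.40 ± 0.14 for Cpeb2 and 2.32 ± 0.33 for mt-Ti, a snoRNA, a synaptonemal complex gene, an mRNA-binding protein gene and a mitochondrial tRNA. The largest decreases were -4.10 ± 1.11 for Snord118, -3.47 ± 0.45 for Dct and -3.40 ± 0.24 for Dcn, with Snord118 (U8) a snoRNA of ribosomal RNA processing, Dct a melanin synthesis gene and Dcn a collagen-binding matrix gene (largest adjusted p = 0.00678 over these 8). Of 12 measured immediate early genes, 11 were higher and 1 lower (11 higher and 1 lower adjusted over the list alone, camera q = 0.000701, est. q = 0.115), with 1.83 ± 0.07 for Zfp36. Of 16 measured circadian clock genes, 14 were higher (14 adjusted over the list alone, camera q = 0.00044, est. q = 0.304), with 1.54 ± 0.11 for Ciart. Of 7 measured mitochondrially encoded mRNAs, 6 were higher (6 adjusted over the list alone, camera q = 0.168, est. q = 0.463), with 1.15 ± 0.14 for mt-Nd5. Of the genes of the cytoplasmic ribosome, 1 of 76 measured ribosomal protein genes was higher and 70 lower (1 higher and 71 lower adjusted over the list alone, camera q = 1.94e-07, est. q = 0.463), among them -1.01 ± 0.07 for Rpl4. Of 11 measured endothelial genes, 11 were lower (11 adjusted over the list alone, camera q = 3.94e-07, est. q = 0.0242), with -2.26 ± 0.15 for Cdh5. As for other cell types, 12 of 12 measured macrophage and leukocyte genes were lower (12 adjusted over the list alone, camera q = 4.85e-05, est. q = 0.115), with -1.83 ± 0.15 for Mrc1, and 9 of 9 measured fibroblast and extracellular matrix genes were lower (9 adjusted over the list alone, camera q = 0.00044, est. q = 0.0684), with -3.40 ± 0.24 for Dcn. Among hepatocyte genes, 4 of 20 measured genes were higher and 15 lower (4 higher and 15 lower adjusted over the list alone, camera q = 0.00196, est. q = 0.304), with -1.67 ± 0.09 for F2. Of the Cyp3a genes only Cyp3a11 (0.88 ± 0.35) and Cyp3a59 (1.03 ± 0.36) passed, each losing its call when 1 library was left out. Counts on Mir122, the hepatocyte miRNA gene, changed by 3.17 ± 0.28, more so on LFD.

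In that comparison 4092 of 10865 tested genes were higher and 3903 lower in pull-down (n = 6 against n = 6), and 4798 higher and 3150 lower when libraries were scaled to total counts, which moved the median of all genes from 0.02 to 0.27. Ribosomal protein genes share reads with their pseudogenes, and the snoRNAs and tRNAs lie in or beside longer transcripts. Their own levels are thus uncertain, as is that of Mir122 in mRNA libraries.

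In kidney mRNA the pull-down was higher, at 4.11 ± 0.44 for Prob1 and 3.81 ± 0.47 for Zscan25, a proline-rich protein gene and a zinc finger gene, and lower, at -5.99 ± 0.60 for Snord13 and -4.92 ± 0.46 for mt-Tv, a snoRNA and a mitochondrial tRNA (largest adjusted p = 4.67e-05, n = 5 each). Cyp3a13 was higher at 8.06 ± 2.82 against 2.9 ± 2.73 CPM (1.68 ± 0.36), with the larger rise on HFD in the levels given above (interaction with diet 2.99 ± 0.71, adjusted p = 0.263, or 0.00116 with no filter on low counts), as were 1.69 ± 0.57 for Cyp3a11 and 3.29 ± 0.66 for Cyp3a59, the call for Cyp3a11 being lost when 1 library was left out. Of 17 measured circadian clock genes, 12 were higher (13 adjusted over the list alone, camera q = 8.36e-05, est. q = 0.188), with 1.54 ± 0.18 for Ciart. Of 16 measured kidney epithelial genes, 12 were lower (1 higher and 12 lower adjusted over the list alone, camera q = 6.84e-05, est. q = 0.224), with -2.32 ± 0.20 for Kap. In the ribosome, 1 of 78 measured ribosomal protein genes was higher and 56 lower (2 higher and 56 lower adjusted over the list alone, camera q = 3e-19, est. q = 0.224), with -2.49 ± 0.17 for Rps27. In the stroma, 13 of 13 measured fibroblast and extracellular matrix genes were lower (13 adjusted over the list alone, camera q = 0.000127, est. q = 0.324), with -2.92 ± 0.31 for Dcn, and 9 of 10 measured endothelial genes were lower (10 adjusted over the list alone, camera q = 0.00012, est. q = 0.324), with -2.38 ± 0.24 for Emcn. Altogether 3992 of 15023 genes were higher and 3946 lower (n = 5 against n = 5), 5071 and 2895 with total-count scaling, which moved the median from 0.01 to 0.23.

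The enrichment in liver minus that in kidney was tested as an interaction. Passing genes above 0 included the transcription factor gene Sim1, at 0 counts in liver input and 0.747 ± 0.122 CPM in HFD pull-down while its kidney level went from 19.4 ± 5.76 in HFD input to 12.3 ± 5.63, Nr0b2, a nuclear receptor gene that represses bile acid synthesis, and Greb1, all 3 with too few counts in a fraction for a fold, and the others were led by 3.95 ± 0.51 for Snai2 and 3.94 ± 0.49 for Rnf144b. Genes below 0 included Fmnl1, Gk5, Hoxa3, Tmem26 and Arhgef39, whose liver pull-down counts were 0 or too few for a fold. Fmnl1, a formin gene, stood at 168 ± 12 CPM in kidney HFD pull-down against 78.4 ± 16 in input, and at 0 in liver HFD pull-down against 1.43 ± 0.82 in input (n = 3 each, largest adjusted p = 0.0453 over these 10 genes). Cyp3a59 also passed (-2.37 ± 0.72). Of 13 measured mitochondrial tRNAs, 3 were higher (3 adjusted over the list alone, camera q = 1.75e-05, est. q = 0.489), with 2.54 ± 0.66 for mt-Tf and 2.34 ± 0.61 for mt-Te. In the cholesterol pathway 1 of 21 measured genes was higher and 6 lower (2 higher and 6 lower adjusted over the list alone, camera q = 0.206, est. q = 0.489), with -1.02 ± 0.20 for Nsdhl. For hepatocyte genes, 2 of 20 measured genes were lower (2 adjusted over the list alone, camera q = 0.514, est. q = 0.922), with -2.96 ± 0.42 for Ambp. The difference passed for 510 genes with more enrichment in liver and 1213 with more in kidney, of 13724 tested (n = 11 pull-downs against n = 11 inputs), and the split depended on scaling, at 747 and 807 with DESeq2-type size factors and 834 and 640 with total counts (median of all genes -0.19 and -0.01). The count was 1046 with the replicate number as a block, 1148 without kidney input LFD 1 and 2628 without liver input LFD 1, and leaving out 1 library ended 11 of the 26 rule-named calls, Sim1, Greb1, Hoxa3, Cyp3a59, Ambp and mt-Te among them.

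In liver small RNA the pull-down was higher, at 2.46 ± 0.33 for Ikzf5 and 2.30 ± 0.30 for Ythdc2, genes of a zinc finger transcription factor and an m6A-binding helicase (n = 5 pull-downs, n = 6 inputs, largest adjusted p = 1.26e-05). The asparagine tRNA gene chr3.tRNA757-AsnGTT had 85.1 ± 41.5 CPM in input and 0 counts in pull-down, at least 413-fold lower with a floor of 3 counts over the group, and Rnft2 was at least 175-fold lower. Cd3e, a T cell receptor complex gene overlapped by other transcripts, fell to 1.67 ± 2.67 against 500.2 ± 223 CPM, and the glutamine tRNA gene chr11.tRNA1493-GlnTTG to 0.0703 ± 0.157 against 65.4 ± 40.9 CPM, too few counts for a fold. Of the snoRNAs, 40 of 40 measured C/D box ones were lower (40 adjusted over the list alone, camera q = 2.54e-25, est. q = 0.167), with -6.05 ± 0.43 for Snord118. Also, 18 of 18 measured H/ACA box snoRNAs were lower (18 adjusted over the list alone, camera q = 7.07e-16, est. q = 0.167), with -4.53 ± 0.35 for Snora34. Of 40 measured miRNAs, 1 was higher and 35 lower (1 higher and 38 lower adjusted over the list alone, camera q = 2.26e-19, est. q = 0.172), with Mir339 at least 73.9-fold lower and Mir148a at -6.57 ± 0.58. Of 12 measured mitochondrial tRNAs, 12 were lower (12 adjusted over the list alone, camera q = 2.85e-10, est. q = 0.167), with -4.35 ± 0.30 for mt-Tt. Of 20 measured hepatocyte genes, 14 were lower (14 adjusted over the list alone, camera q = 0.0317, est. q = 0.477), with -1.44 ± 0.24 for Apoc3, but with total-count scaling Alb, Ambp and Apoh changed sign, 8 were higher and 0 lower, and the list's median went from -0.91 to 0.25. Of 13 measured macrophage and leukocyte genes, 13 were lower (13 adjusted over the list alone, camera q = 7.88e-09, est. q = 0.167), with -2.30 ± 0.23 for Csf1r. Mir122 changed by -3.11 ± 0.39 and Alb by -1.10 ± 0.26. There were 2262 genes higher and 2372 lower of 8401, and 5720 and 705 with total-count scaling, which moved the median of all genes from 0.10 to 1.23. Whether counting used the strand is not stated, and whether snoRNA and miRNA counts include reads of host transcripts was not tested.

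In VsWAT small RNA the pull-down was higher, at 4.37 ± 1.20 for Atcay, 2.80 ± 0.15 for Rgcc and 2.68 ± 0.28 for Sucnr1 (n = 6 each, largest adjusted p = 0.0176), with Rgcc a cell cycle regulator gene and Sucnr1 the succinate receptor gene. Decreases included Cd3e at 1.54 ± 1.59 against 276 ± 51.7 CPM, chr11.tRNA1493-GlnTTG at 0.184 ± 0.308 against 40.8 ± 16.9 CPM and Mir484 at 0.225 ± 0.351 against 50.2 ± 6.31 CPM, the last 2 with too few pull-down counts for a fold, and -7.12 ± 0.25 for Ppp1r14a and -7.04 ± 0.54 for Gabbr2, although Cd3e, Ppp1r14a and Gabbr2 overlap other transcripts. Of 7 measured mitochondrially encoded mRNAs, 7 were higher (7 adjusted over the list alone, camera q = 3.55e-10, est. q = 0.0815), with 2.59 ± 0.26 for mt-Cytb. Of 15 measured adipocyte genes, 9 were higher and 3 lower (9 higher and 3 lower adjusted over the list alone, camera q = 0.0292, est. q = 0.132), with 2.19 ± 0.22 for Pparg. Of hepatocyte genes counted in this tissue, 1 of 20 measured genes was higher and 3 lower (1 higher and 1 lower adjusted over the list alone, camera q = 0.763, est. q = 0.943), with -1.95 ± 0.42 for Trf. Of 14 measured fibroblast and extracellular matrix genes, 13 were lower (13 adjusted over the list alone, camera q = 3.4e-11, est. q = 0.0241), with -1.80 ± 0.15 for Pdgfra. Of 17 measured macrophage and leukocyte genes, 14 were lower (14 adjusted over the list alone, camera q = 2.85e-11, est. q = 0.0366), with -1.93 ± 0.14 for Csf1r after Cd3e. Among short non-coding RNAs 38 of 41 measured C/D box snoRNAs were lower (38 adjusted over the list alone, camera q = 4.04e-62, est. q = 0.0241), with -5.77 ± 0.19 for Snord91a. Of 63 measured miRNAs, 46 were lower (47 adjusted over the list alone, camera q = 2.24e-20, est. q = 0.128), with -6.52 ± 0.30 for Mir328. Of 15 measured circadian clock genes, 7 were higher (7 adjusted over the list alone, camera q = 0.0335, est. q = 0.0996), with 0.93 ± 0.13 for Nr1d2. With total-count scaling 12 adipocyte genes were higher and 0 lower, 13 clock genes higher, and 2 hepatocyte genes higher and 1 lower. Alb changed by -0.83 ± 0.94 and did not pass, and Mir122 by -1.50 ± 0.78.

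Of 11339 genes tested in VsWAT small RNA, 2374 were higher and 2601 lower, and 5320 and 1129 with total-count scaling, which moved the median of all genes from 0.01 to 0.64. Without the replicates whose input held over 300 CPM of Alb, 1587 genes passed.

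GAS small RNA was higher in pull-down, at 4.33 ± 0.43 for Lin52 and 4.27 ± 0.22 for Myf6, where Myf6 encodes a muscle transcription factor (n = 6 each, largest adjusted p = 6.07e-08). Pull-down counts of chr3.tRNA757-AsnGTT were 0 against 181 ± 61.2 CPM in input, at least 1040-fold lower, chr11.tRNA1493-GlnTTG at 0.0966 ± 0.237 against 148 ± 49.6 CPM had too few counts for a fold, and other decreases were led by -8.41 ± 0.46 for Cd3e. Of 7 measured mitochondrially encoded mRNAs, 7 were higher (7 adjusted over the list alone, camera q = 8.41e-09, est. q = 0.0874), with 3.28 ± 0.25 for mt-Cytb. Of 42 measured C/D box snoRNAs, 42 were lower (42 adjusted over the list alone, camera q = 2.76e-57, est. q = 0.0315), with -7.15 ± 0.27 for Snord23. Of 57 measured miRNAs, 2 were higher and 51 lower (2 higher and 51 lower adjusted over the list alone, camera q = 8.64e-26, est. q = 0.0625), with -4.61 ± 0.23 for Mir23b. Of 13 measured fibroblast and extracellular matrix genes, 13 were lower (13 adjusted over the list alone, camera q = 1.16e-09, est. q = 0.0874), with -2.37 ± 0.18 for Dcn. Of 18 measured skeletal muscle genes, 1 was higher and 8 lower (1 higher and 8 lower adjusted over the list alone, camera q = 0.215, est. q = 0.785), with -1.20 ± 0.21 for Atp2a1, but with total-count scaling Ttn changed sign, 11 were higher and 0 lower, and the list's median went from -0.37 to 0.57. In all 2735 of 9797 genes were higher and 2592 lower, 5553 and 1104 with total-count scaling, which moved the median from 0.06 to 0.97.

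Enrichment in VsWAT minus that in GAS was above 0 for the tRNA genes chr13.tRNA85-LeuCAA and chr3.tRNA757-AsnGTT and for Paqr4, a progestin receptor family gene, all 3 with 0 or too few GAS pull-down counts for a fold, and largest of the others at 4.18 ± 0.84 for chr13.tRNA960-ArgTCG. It was below 0 for the muscle gene Myf6, at 499 ± 181 CPM in GAS HFD pull-down against 29.9 ± 4.27 in input and at 0 in VsWAT pull-down (n = 3 each), and for Muc16, Csrp3 and Mylk4, a mucin gene and more muscle genes, also with 0 or too few counts for a fold (largest adjusted p = 0.0364). Of 12 measured mitochondrial tRNAs, 9 were higher (11 adjusted over the list alone, camera q = 2.78e-11, est. q = 0.32), with 3.41 ± 0.61 for mt-Tl2. Of 15 measured adipocyte genes, 5 were higher (6 adjusted over the list alone, camera q = 0.000416, est. q = 0.0957), with 2.19 ± 0.28 for Lipe, and 4 of 19 measured H/ACA box snoRNAs were higher (9 adjusted over the list alone, camera q = 0.000738, est. q = 0.877), with 2.14 ± 0.45 for Snora31. The difference passed for 880 genes more enriched in VsWAT and 642 more enriched in GAS, of 12454 tested (n = 12 against n = 12), with 487 and 1014 under total-count scaling (median of all genes 0.04 and -0.20). It passed for 541 genes without the VsWAT replicates with over 300 CPM of Alb in input, and leaving out 1 library ended the calls of Myf6 and Csrp3.

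Plasma was the thinnest tissue in counts, and over genes with at least 50 counts in a pair its pull-down replicates correlated at -0.128 on HFD and -0.155 on LFD, against 0.692 and 0.61 in input. Its higher genes were led by mitochondrial mRNAs and a miRNA, at 6.68 ± 0.97 for mt-Nd2, 6.61 ± 1.48 for Mir301, 6.59 ± 1.05 for mt-Nd1 and 6.53 ± 0.97 for mt-Nd4 (n = 4 each, largest adjusted p = 0.0336). Mir484 and Cfap161, a cilium gene, had 0 counts in all 4 pull-downs and were at least 522-fold and 193-fold lower, and the tRNA genes chr2.tRNA1509-SerGCT and chr13.tRNA98-ValCAC went from 9606 and 488 to 32.8 and 0.589 CPM. Of 7 measured mitochondrially encoded mRNAs, 7 were higher (7 adjusted over the list alone, camera q = 6.84e-16, est. q = 0.139), and mt-Nd2 stood at 2390 ± 1509 against 22.8 ± 9.95 CPM. Of 14 measured hepatocyte genes, 1 was higher (4 adjusted over the list alone, camera q = 4.22e-06, est. q = 0.358), that of Apob (5.83 ± 1.36), with Alb at 4.05 ± 1.28 and Mir122 at -1.43 ± 0.94 not passing. Of 7 measured erythroid genes, 2 were lower (6 adjusted over the list alone, camera q = 0.000209, est. q = 0.358), with -4.19 ± 0.70 for Hba-a1. With total-count scaling 0 erythroid genes were lower, their median going from -2.39 to -0.28, and 5 hepatocyte genes were higher, and with DESeq2-type size factors 1 and 0. Of 50 measured miRNAs, 1 was higher and 2 lower (3 higher and 15 lower adjusted over the list alone, camera q = 0.0056, est. q = 0.515), with -4.36 ± 0.95 for Mir328, and the miRNA median changed sign from -2.07 to 0.01 with total-count scaling. Only 11 genes were higher and 22 lower of 3469 tested, 68 and 6 with total-count scaling (median of all genes 0.04 and 2.11), 10 and 10 with DESeq2-type size factors, and 73 in all by DESeq2. The count was 53 without input HFD 1, 60 without input LFD 2, 163 and 360 without pull-down HFD 1 and 2 and 121 and 0 without pull-down LFD 1 and 2, and 0 of the 13 rule-named calls held in every such run.

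Mitochondrially encoded mRNAs took a larger share of counts in pull-down than in input in every tissue. Their share was 14.3% ± 1.88 against 7.94% ± 1.20 in liver mRNA (SD, n = 6 each, exact permutation adjusted p = 0.00764), 18.9% ± 1.52 against 13.9% ± 2.89 in kidney mRNA (n = 5 each, exact permutation adjusted p = 0.0289) and 10.5% ± 2.46 against 4.04% ± 0.68 in liver small RNA (n = 5 and n = 6, exact permutation adjusted p = 0.0104). It rose from 1.87% ± 0.223 to 14.7% ± 3.76 in VsWAT and from 2.64% ± 0.418 to 27.9% ± 2.66 in GAS (n = 6 each, exact permutation adjusted p = 0.00764 in both), and from 0.016% ± 0.00676 to 2.99% ± 1.39 in plasma (n = 4 each, exact permutation adjusted p = 0.0399). Mitochondrial rRNA took less of the pull-down in liver small RNA (18.1% against 27.9%), VsWAT (14.0% against 25.6%) and GAS (16.6% against 37.3%), and more in plasma (4.78% against 1.04%). Small RNA classes shrank in the tissue pull-downs, with miRNA at 0.724% against 2.66% in liver, 0.357% against 1.62% in VsWAT and 0.339% against 2.06% in GAS, and snoRNA at 0.455% against 3.19%, 0.384% against 3.11% and 0.441% against 3.42%. In plasma the miRNA share was 2.14% ± 0.414 in pull-down and 1.69% ± 0.819 in input (n = 4 each, exact permutation adjusted p = 0.405) and did not pass, while rRNA made up 4.10% against 12.7%. Without the most abundant gene of each library the mitochondrial mRNA share was higher by 0.414 percentage points in kidney in place of 4.93 and by 4.11 in liver mRNA in place of 6.33, the mitochondrial rRNA share lower by 13 in GAS in place of 20.7, and in plasma the rRNA share lower by 20.1 in place of 8.59 and the miRNA share lower by 0.895 in place of higher by 0.448. These 2-sided tests form a family of 60.

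**Figure D1:**
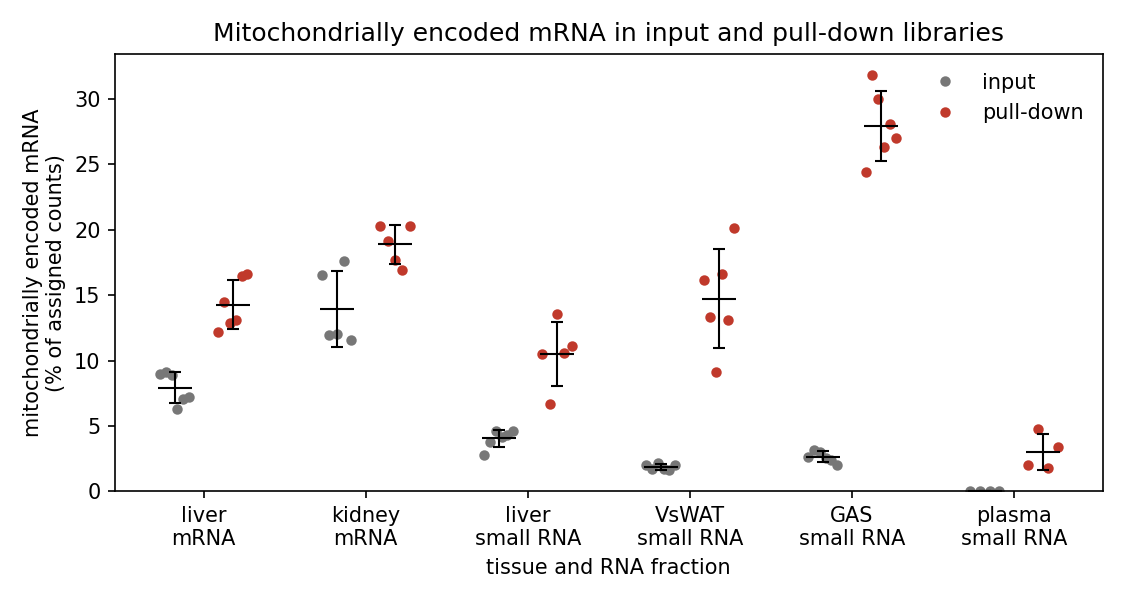
Percent of assigned counts on mitochondrially encoded mRNAs (vertical axis) in input and pull-down libraries of each tissue and RNA type (horizontal axis), with 1 point per library, a dash for the mean and an error line for the SD.

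Tissues shared many of the genes that were higher in pull-down. Of genes tested in both small RNA sets, 1095 were higher in liver and VsWAT where independent calls would give 519, 1093 in liver and GAS where they would give 575, and 1380 in VsWAT and GAS where they would give 593. Plasma shared 8 with VsWAT (2.46 if independent), 7 with GAS (2.21) and 0 with liver (2.86). For lower genes the numbers were 1257 for liver and VsWAT (449.97 if independent), 1206 for liver and GAS (479.1) and 1576 for VsWAT and GAS (570.07), and plasma shared 20 with VsWAT (6.09), 19 with GAS (7.84) and 19 with liver (6.39).

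On HFD, liver mRNA input lost transcripts of fatty acid synthesis, and Scd1, the stearoyl-CoA desaturase gene, fell to 199 ± 10.7 against 12420 ± 2441 CPM (-5.96 ± 0.21, n = 3 each). The genes next in size of decrease were -5.01 ± 0.35 for Slc2a4, -5.00 ± 0.22 for Ppp1r3g, -4.11 ± 0.33 for Fasn and -3.57 ± 0.46 for Acacb, genes of the insulin-responsive glucose transporter, a glycogen regulator, fatty acid synthase and an acetyl-CoA carboxylase. Increases included Snord82 at 9.79 ± 0.915 against 0.083 ± 0.144 CPM, a snoRNA with too few LFD counts for a fold, Mir122 at 39 ± 9.99 against 1.75 ± 1.42 CPM, and 3.45 ± 0.20 for Cyp26a1 and 3.17 ± 0.15 for Creld2, with Cyp26a1 degrading retinoic acid and Creld2 responding to stress of the endoplasmic reticulum (ER) (largest adjusted p = 0.00885 over these 9). Naming required that HFD and LFD libraries did not overlap, a separation that chance gives 10% of genes at 3 against 3. Of 16 measured fatty acid synthesis genes, 10 fell (10 adjusted over the list alone, camera q = 2.18e-22, est. q = 0.0537), with -2.48 ± 0.14 for Acaca. Of 14 measured genes on the list of gluconeogenesis and glycolysis, 6 fell (10 adjusted over the list alone, camera q = 1.5e-06, est. q = 0.0764), with -1.52 ± 0.11 for Igfbp1, an IGF-binding protein gene. Of 15 measured ER stress genes, 8 rose (9 higher and 1 lower adjusted over the list alone, camera q = 7.02e-10, est. q = 0.17), with 1.46 ± 0.10 for Hsp90b1. Of 18 measured major urinary protein genes, 3 rose and 1 fell (7 higher and 1 lower adjusted over the list alone, camera q = 1.5e-06, est. q = 0.0537), with 1.79 ± 0.17 for Mup4. Of 15 measured bile acid and xenobiotic genes, 1 rose and 7 fell (1 higher and 7 lower adjusted over the list alone, camera q = 0.0275, est. q = 0.309), with 2.05 ± 0.10 for Cyp7b1. Alb changed by -0.81 ± 0.13.

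Liver mRNA input had 505 genes higher and 823 lower on HFD of 10177 tested (n = 3 against n = 3). The count was 48, 56 and 52 without HFD 1, 2 and 3 and 5582, 166 and 176 without LFD 1, 2 and 3, 2439 when the dispersion came from all 4 groups of the tissue, and 0 by edgeR when near-identical libraries were summed, leaving 2 against 2. Leaving out any 1 library kept 19 of the 34 rule-named calls, including Scd1, Slc2a4, Fasn, Acaca, Creld2 and Hspa5, and reversed none, and members of the Mup family share reads.

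In liver mRNA pull-down Scd1 was again lower on HFD, at 84.9 ± 3.7 against 5720 ± 1179 CPM (-6.07 ± 0.15, n = 3 each), with -4.61 ± 0.26 for Ppp1r3g and -4.12 ± 0.46 for Slc2a4. Higher genes were led by 2.73 ± 0.25 for Sdf2l1, 2.72 ± 0.16 for Selenbp2 and 2.34 ± 0.14 for Creld2, with Sdf2l1 an ER chaperone gene and Selenbp2 a selenium-binding protein gene (largest adjusted p = 1.93e-07 over these 6). Of 16 measured fatty acid synthesis genes, 15 fell (15 adjusted over the list alone, camera q = 1.56e-73, est. q = 0.000877), with -2.20 ± 0.10 for Elovl6. Of 15 measured ER stress genes, 11 rose (14 adjusted over the list alone, camera q = 1.49e-28, est. q = 0.00597), with 1.61 ± 0.10 for Manf. Of 14 measured genes on the list of gluconeogenesis and glycolysis, 1 rose and 8 fell (1 higher and 8 lower adjusted over the list alone, camera q = 5.67e-11, est. q = 0.0139), with -1.18 ± 0.09 for Igfbp1. Of 18 measured major urinary protein genes, 9 rose and 1 fell (11 higher and 1 lower adjusted over the list alone, camera q = 6.33e-06, est. q = 0.251), with 1.54 ± 0.13 for Mup11 and 1.00 ± 0.15 for Mup7. In the pull-down 761 genes were higher and 810 lower of 10085, or 674 in all with the dispersion of all 4 groups, and leaving out 1 library ended 2 of the 25 rule-named calls, Mup7 and Mup17.

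The diet effect in liver pull-down minus that in input passed for 200 genes above 0 and 165 below, of 10865. It was highest at 2.66 ± 0.51 for Gapdh and 2.60 ± 0.49 for Ppdpf, a glycolysis gene that shares reads with its pseudogenes and a pancreas progenitor factor gene. It was below 0 for Snord82, whose LFD input held too few counts for a fold, and lowest of the others at -3.81 ± 0.57 for Mir122 and -2.52 ± 0.49 for Lepr, with Lepr the leptin receptor gene (largest adjusted p = 0.0243). The numbers were 170 and 218 with DESeq2-type size factors, 745 in all by DESeq2 and 0 by edgeR with near-identical libraries summed. With the replicate number as a block 0 genes passed. The count was 46, 40 and 110 without input HFD 1, 2 and 3, 3054, 76 and 154 without input LFD 1, 2 and 3, 18, 14 and 133 without pull-down HFD 1, 2 and 3 and 59 and 30 without pull-down LFD 2 and 3, and Mir122 alone of the 8 rule-named calls held in every such run.

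In kidney mRNA no gene passed in either fraction, where HFD had 3 libraries and LFD 2. The smallest p in input belonged to the immediate early gene Egr1 (-2.46 ± 0.20, adjusted p = 0.0838), the immunoglobulin gene Ighg3 at 5.51 ± 0.793 against 0.0324 ± 0.0458 CPM, with too few LFD counts for a fold, and the chemokine gene Cxcl1 (-3.04 ± 0.29). As a set 0 of 14 measured immediate early genes passed (9 lower adjusted over the list alone, camera q = 4.19e-20, est. q = 0.144), with -2.19 ± 0.26 for Fos. Also, 0 of 78 measured ribosomal protein genes passed (5 higher adjusted over the list alone, camera q = 8.49e-09, est. q = 0.486), with 1.78 ± 0.31 for Rps10. In the pull-down the smallest p belonged to -1.10 ± 0.25 for Smpdl3a, -1.79 ± 0.43 for Dcn and -1.01 ± 0.25 for Rps21 (adjusted p = 0.942 for Smpdl3a, a phosphodiesterase gene), while 0 of 76 measured ribosomal protein genes passed (11 lower adjusted over the list alone, camera q = 6.37e-25, est. q = 0.534), with -0.86 ± 0.21 for Rps20, and 0 of 16 measured kidney epithelial genes passed (4 lower adjusted over the list alone, camera q = 1.43e-07, est. q = 0.534), with -0.92 ± 0.26 for Umod. By edgeR 0 of 14273 genes passed in input, with 1956 at an unadjusted p under 0.05, 144 past the threshold by DESeq2, 1536 with no filter on low counts and 6722 without HFD 1 and LFD 1, which leaves a lone LFD library assumed to vary like the HFD ones. The input count was 1647 without HFD 1. In pull-down 0 of 12362 passed, with 631 at an unadjusted p under 0.05, 0 by DESeq2 and 10 with no filter, and 463 without LFD 2.

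The diet effect in liver input minus that in kidney input was below 0 for the acetylcholine receptor gene Chrna4, at 0 on HFD against 10.1 ± 4.2 CPM on LFD in liver (n = 3 each) and 15.3 ± 3.16 against 13.8 ± 5.67 in kidney (n = 3 and n = 2), for the prothrombin gene F2, at 0 in kidney LFD input, and at -5.43 ± 0.51 for Slc2a4 and -4.75 ± 0.41 for Scd1. It was above 0 for Snord82, with too few liver LFD counts for a fold, and at 6.75 ± 1.06 for Snord49a and 4.84 ± 0.58 for Cxcl1 (largest adjusted p = 0.043 over these 7). Of 17 measured fatty acid synthesis genes, 9 were lower (10 adjusted over the list alone, camera q = 4.37e-13, est. q = 0.0618), with -1.92 ± 0.23 for Acss2 and -2.46 ± 0.32 for Me1. Of 16 measured ER stress genes, 4 were higher (7 higher and 2 lower adjusted over the list alone, camera q = 0.00014, est. q = 0.307), with 2.66 ± 0.26 for Creld2 and 1.74 ± 0.24 for Hsp90b1, and 1 of 13 measured immediate early genes was higher (5 adjusted over the list alone, camera q = 0.000128, est. q = 0.101), that of Egr1 (3.35 ± 0.25). This difference passed for 33 genes above 0 and 91 below, of 13179, for 1138 in all by DESeq2 and for 6 with near-identical libraries summed, and the count was 17, 22 and 13 without liver HFD 1, 2 and 3, 316, 27 and 34 without liver LFD 1, 2 and 3, 2527, 24 and 25 without kidney HFD 1, 2 and 3 and 26 and 853 without kidney LFD 1 and 2. Such runs ended the calls of Chrna4, F2, Snord49a, Me1 and Hsp90b1.

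Liver small RNA input showed 2.84 ± 0.41 for Egr1, 2.57 ± 0.34 for Chka and 2.49 ± 0.37 for Cish higher and Scd1 lower on HFD (-4.96 ± 0.53, 306 ± 192 against 9537 ± 2089 CPM, n = 3 each, largest adjusted p = 0.0352), where Chka encodes choline kinase and Cish a suppressor of cytokine signalling. Its pull-down showed 2.68 ± 0.40 for Egr1 and 2.54 ± 0.34 for Nfil3 higher and -4.23 ± 0.37 for Scd1 and -2.95 ± 0.37 for Hamp2 lower (n = 3 and n = 2, largest adjusted p = 0.0351), where Nfil3 encodes a circadian repressor and Hamp2 a hepcidin. In input 1 of 16 measured fatty acid synthesis genes fell (12 adjusted over the list alone, camera q = 5.04e-27, est. q = 0.218) and 1 of 9 measured immediate early genes rose (7 adjusted over the list alone, camera q = 1.79e-13, est. q = 0.127), Scd1 and Egr1 themselves. In pull-down 1 of 16 measured fatty acid synthesis genes fell (11 adjusted over the list alone, camera q = 3.52e-24, est. q = 0.32) and 1 of 11 measured immediate early genes rose (6 adjusted over the list alone, camera q = 2.44e-13, est. q = 0.241), again Scd1 and Egr1. The input count was 4 higher and 2 lower of 5421, 55 by DESeq2, and 2, 0 and 10 without HFD 1, 2 and 3 and 1, 1 and 13 without LFD 1, 2 and 3. For the pull-down it was 3 and 2 of 9167, 36 by DESeq2, and 1, 1 and 33 without HFD 1, 2 and 3 and 16 without LFD 3. Of the calls named here, Scd1 in pull-down alone held in every such run.

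In VsWAT total RNA the genes that rose most on HFD were 2.13 ± 0.17 for Peg3, 2.06 ± 0.16 for Lrg1, 1.82 ± 0.19 for Btc and 1.72 ± 0.23 for Sfrp5, genes of an imprinted zinc finger protein, a leucine-rich glycoprotein, an EGF family ligand and a Wnt inhibitor (n = 3 each). Of passing genes, those that fell most were -3.87 ± 0.38 for Acly, -3.13 ± 0.27 for Thrsp and -1.77 ± 0.25 for Slc5a6, with Acly at 67.1 ± 2.06 against 982 ± 483 CPM, the ATP citrate lyase gene, Thrsp a lipogenesis regulator gene and Slc5a6 a vitamin transporter gene (largest adjusted p = 0.0328 over these 7). Of 16 measured fatty acid synthesis genes, 2 fell (13 adjusted over the list alone, camera q = 2.29e-34, est. q = 0.174), those of Thrsp and Acly, whereas 0 of 20 measured cholesterol synthesis genes passed (7 lower adjusted over the list alone, camera q = 9.96e-07, est. q = 0.489), with -1.29 ± 0.28 for Dhcr7, and 0 of 13 measured immediate early genes passed (6 higher adjusted over the list alone, camera q = 5.82e-07, est. q = 0.489), with 0.61 ± 0.13 for Btg2. Of 14 measured circadian clock genes, 2 fell (7 adjusted over the list alone, camera q = 0.000195, est. q = 0.174), with -1.24 ± 0.15 for Nr1d1. Of 10 measured genes on the list of gluconeogenesis and glycolysis, 1 fell (6 adjusted over the list alone, camera q = 9.96e-07, est. q = 0.489), the glucose transporter gene Slc2a4 (-1.60 ± 0.22). Passing genes numbered 8 higher and 16 lower of 12385, 196 in all by DESeq2, 621 with no filter and 966 without the libraries with over 3% of Gm42418, which leaves 2 against 1 with the lone library assumed to vary like the others. The count was 4, 5 and 10 without HFD 1, 2 and 3 and 81, 50 and 63 without LFD 1, 2 and 3, and of the rule-named calls only Peg3 and Lrg1 held in each of these runs.

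VsWAT small RNA input repeated part of this, with 2.18 ± 0.21 for Lrg1, 1.67 ± 0.27 for Rpl23a and 1.35 ± 0.22 for Sfrp5 higher on HFD and -3.58 ± 0.34 for Acly, -3.49 ± 0.38 for Tkt and -3.16 ± 0.33 for Fasn lower (n = 3 each, largest adjusted p = 0.0159), Tkt being the transketolase gene. Its pull-down had 2.88 ± 0.40 for Slc5a7 and 2.04 ± 0.29 for Peg3 higher, the first a choline transporter gene, and -3.67 ± 0.54 for Rdh12, -3.37 ± 0.37 for Acly and -3.03 ± 0.36 for Acaca lower, the first a retinol dehydrogenase gene (largest adjusted p = 0.0211). In input 4 of 16 measured fatty acid synthesis genes fell (11 adjusted over the list alone, camera q = 2.24e-38, est. q = 0.0918), with -3.01 ± 0.25 for Thrsp, and 0 of 11 measured immediate early genes passed (6 higher adjusted over the list alone, camera q = 1.85e-08, est. q = 0.268), with 1.26 ± 0.34 for Fos. In pull-down 5 of 16 measured fatty acid synthesis genes fell (7 adjusted over the list alone, camera q = 5.33e-29, est. q = 0.0922), with -2.22 ± 0.29 for Thrsp, and 0 of 13 measured fibroblast and extracellular matrix genes passed (6 higher adjusted over the list alone, camera q = 1.32e-09, est. q = 0.124), with 0.87 ± 0.23 for Col1a2. Input calls numbered 7 higher and 10 lower of 7987, 70 in all by DESeq2, 6 with the near-identical HFD 1 and 2 summed, and 5 and 8 without HFD 1 and 2 and 68 and 62 without LFD 1 and 2. Pull-down calls numbered 2 and 9 of 10712, 79 by DESeq2, and 0, 0 and 5 without HFD 1, 2 and 3 and 6 without LFD 3. Of these calls only Lrg1, Acly, Fasn and Thrsp in input held in every such run.

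In GAS total RNA adipocyte genes were lower on HFD. Fabp4, a fatty acid-binding protein gene, stood at 172 ± 25.2 against 608 ± 68.9 CPM (n = 3 each). Whether fat content differed between the samples was not tested. The largest decreases were -3.36 ± 0.59 for Kcnj15, -3.31 ± 0.36 for Slc25a1, -3.29 ± 0.45 for Thrsp and -3.00 ± 0.42 for Scd1. Kcnj15 is a potassium channel gene and Slc25a1 the citrate carrier gene. The largest increases were 2.25 ± 0.41 for Lrrc52, 2.19 ± 0.37 for Mpc1-ps, 2.10 ± 0.28 for Gapdh and 1.82 ± 0.27 for Gpx4, with Lrrc52 a potassium channel subunit gene (largest adjusted p = 0.0436 over these 8), while Mpc1-ps, Gapdh and Gpx4 share reads with gene copies elsewhere. Of 14 measured adipocyte genes, 8 fell (1 higher and 10 lower adjusted over the list alone, camera q = 1.16e-16, est. q = 0.0746), with -1.82 ± 0.19 for Fabp4, and 1 of 15 measured fatty acid synthesis genes rose and 4 fell (2 higher and 6 lower adjusted over the list alone, camera q = 1.3e-09, est. q = 0.359), with -2.66 ± 0.30 for Acly. Of 18 measured skeletal muscle genes, 2 rose (7 adjusted over the list alone, camera q = 1.74e-10, est. q = 0.454), with 1.04 ± 0.19 for Mybpc2, and 0 of 14 measured H/ACA box snoRNAs passed (8 higher adjusted over the list alone, camera q = 1.09e-08, est. q = 0.553), with 2.56 ± 0.60 for Snora15. Calls numbered 51 higher and 57 lower of 11866, 455 in all by DESeq2. The count was 33 without HFD 1 (over 3% of Gm42418), 1 and 38 without HFD 2 and 3 and 41 and 36 without LFD 1 and 3. Of 23 rule-named calls 0 held in every such run.

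GAS small RNA input had -3.84 ± 0.53 for Fasn, -2.68 ± 0.35 for Tkt and -2.66 ± 0.38 for Acly lower on HFD (n = 3 each, largest adjusted p = 0.00463). Its pull-down had -4.19 ± 0.44 for Fasn, -4.06 ± 0.49 for Agpat2 and -3.68 ± 0.32 for Thrsp lower, Agpat2 being a triglyceride synthesis gene, and 1.63 ± 0.35 for Abr and 1.26 ± 0.23 for Egln3 higher, Egln3 being an oxygen-sensing hydroxylase gene (largest adjusted p = 0.0491). In input 1 of 12 measured adipocyte genes fell (7 adjusted over the list alone, camera q = 4.14e-17, est. q = 0.216), Cidec (-1.68 ± 0.30), and 4 of 14 measured fatty acid synthesis genes fell (5 adjusted over the list alone, camera q = 3.37e-14, est. q = 0.216), with -2.34 ± 0.45 for Scd1. In pull-down 8 of 14 measured adipocyte genes fell (10 adjusted over the list alone, camera q = 1.54e-30, est. q = 0.00535), with -2.14 ± 0.22 for Fabp4. Also, 4 of 13 measured fatty acid synthesis genes fell (6 adjusted over the list alone, camera q = 5.1e-19, est. q = 0.0611), with -2.23 ± 0.35 for Acly and -2.83 ± 0.41 for Scd1, and 4 of 12 measured mitochondrial tRNAs fell (10 adjusted over the list alone, camera q = 2.16e-24, est. q = 0.0765), with -2.30 ± 0.34 for mt-Tf and -2.78 ± 0.40 for mt-Ti. Input calls were 0 higher and 14 lower of 5072, and 3 and 0 without HFD 2 and 3 and 24 and 5 without LFD 1 and 2. Pull-down calls were 4 and 61 of 9058, 111 by DESeq2, and 38, 17 and 17 without HFD 1, 2 and 3. All named input calls were lost in such runs, as were Abr, Egln3, Acly, Scd1 and the tRNAs in pull-down.

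The diet effect in VsWAT total RNA minus that in GAS total RNA was highest at 4.04 ± 0.90 for Wfdc21, 3.34 ± 0.58 for Hp and 3.34 ± 0.71 for Mest, with Hp the haptoglobin gene and Mest an imprinted gene of adipose growth, and lowest at -5.13 ± 0.86 for Mpc1-ps, -3.94 ± 0.67 for Gapdh and -3.42 ± 0.56 for Gpx4, whose reads are shared with gene copies (largest adjusted p = 0.0478). Of 15 measured adipocyte genes, 8 were higher (8 higher and 1 lower adjusted over the list alone, camera q = 1.47e-09, est. q = 0.0781), with 2.02 ± 0.27 for Fabp4. Yet 2 of 16 measured fatty acid synthesis genes were lower (1 higher and 5 lower adjusted over the list alone, camera q = 0.0037, est. q = 0.588), with -2.32 ± 0.49 for Me1. Of 16 measured circadian clock genes, 2 were lower (4 adjusted over the list alone, camera q = 0.00157, est. q = 0.464), with -1.30 ± 0.24 for Cry2, and 0 of 17 measured H/ACA box snoRNAs passed (13 lower adjusted over the list alone, camera q = 2.24e-10, est. q = 0.464), with -3.12 ± 0.73 for Snora73a. This difference passed for 87 genes above 0 and 125 below, of 13622, 832 in all by DESeq2 and 0 without the 4 libraries with over 3% of Gm42418. The count was 17, 15 and 30 without VsWAT HFD 1, 2 and 3, 136 and 68 without VsWAT LFD 1 and 3, 84 and 5 without GAS HFD 1 and 2 and 109, 772 and 72 without GAS LFD 1, 2 and 3, and 0 of the 16 rule-named calls held in every such run.

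In plasma no gene passed between diets (n = 2 each). The smallest p in input belonged to -2.49 ± 0.91 for Fasn and 2.10 ± 0.82 for Pecam1, the second an endothelial adhesion gene, and pull-down genes with a small p included Rassf1, a tumour suppressor gene (5.98 ± 1.75), and Tax1bp1, an autophagy receptor gene with too few HFD counts for a fold. By edgeR 0 of 1197 input genes and 0 of 2590 pull-down genes passed, with 8 and 15 at an unadjusted p under 0.05 and 0 and 0 by DESeq2. The input count was 78 without LFD 1, and the pull-down count 2 without HFD 2.

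Whether the diet changed enrichment was also tested in the other 5 sets. The smallest p belonged to -2.97 ± 0.59 for mt-Ti and -2.70 ± 0.56 for mt-Tf in GAS small RNA, -1.94 ± 0.34 for Rps14 and -2.11 ± 0.38 for Rps10 in kidney mRNA, -2.17 ± 0.61 for Simc1 and -1.69 ± 0.47 for Ppan in liver small RNA and 1.65 ± 0.39 for Sulf1 and -1.73 ± 0.44 for Topbp1 after Snora15 in VsWAT small RNA, among them mitochondrial tRNAs and ribosomal protein genes. In plasma genes with a small p included Tax1bp1 and Pkn2, each with a group of 0 or too few counts for a fold. By edgeR 0 genes passed in GAS, kidney, liver small RNA, plasma and VsWAT, with 415, 1952, 345, 198 and 458 at an unadjusted p under 0.05 and 14, 104, 0, 0 and 2 past the threshold by DESeq2. The kidney count was 1421 without input HFD 1 and 6 without input LFD 1, and the VsWAT count rose to 1 without input LFD 2.

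**Figure D2:**
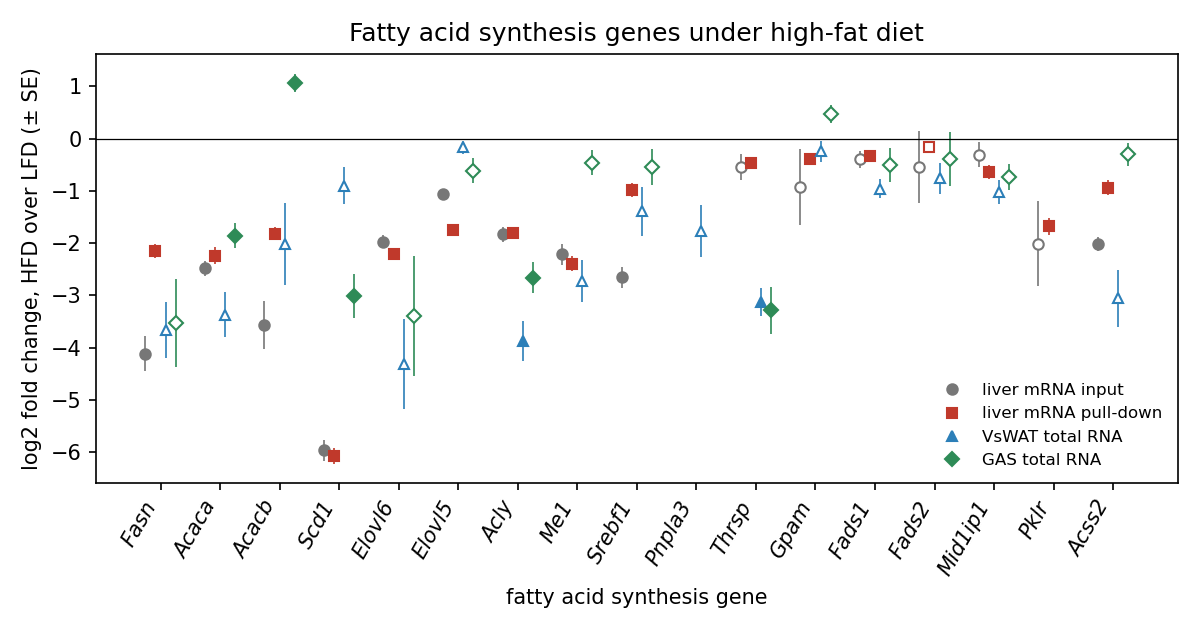
Change on HFD over LFD (vertical axis, log2 fold change, lines for SE) of each fatty acid synthesis gene (horizontal axis) in liver mRNA input, liver mRNA pull-down, VsWAT total RNA and GAS total RNA, with filled symbols for genes that passed and n = 3 libraries per diet. Every estimate was below 0 in the liver and VsWAT sets, and in GAS total RNA those of Acacb (1.07) and Gpam (0.47) were above 0.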

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

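Of the tests below, the correlation of liver with kidney enrichment, the range over all 14 kidney genes and the tests of liver or kidney RNA as the cause of raised genes were written after the results were seen, and the others before. Each of 5 results is listed because the test of a difference between groups called genes: 365 for the diet by pull-down interaction in liver mRNA, 124 for the diet effect in liver minus kidney input, 212 for the diet effect in VsWAT minus GAS total RNA, 1723 for enrichment in liver minus kidney mRNA and 1522 for enrichment in VsWAT minus GAS small RNA.

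Hepatocyte genes were counted in VsWAT libraries, from a source the tests leave open. Over 283 liver genes that GAS total RNA held under 1 CPM, VsWAT total RNA and liver levels had a Spearman rho of 0.421. This lies between the 0.5 set for carried-over liver RNA and the 0.2 set against it. The median ratio was 0.125%. Only 97 of 283 were over 1 CPM in VsWAT, so most levels and ratios lie near the floor. Over 174 kidney genes picked alike the rho with kidney input was -0.00289. Expression in VsWAT itself was not tested. If RNA labelled in liver had moved to VsWAT, hepatocyte genes could be more enriched there. Their median fold change in VsWAT exceeded that in liver small RNA by 0.187 (-0.718 against -0.905, SD 0.926 over 20 genes). Between the limits of 0.5 and 0 this is undecided, and it depends on scaling, as total counts made the liver median positive. Genes are not independent replicates, and no library was a blank pull-down.

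Kidney mRNA showed a pull-down enrichment much like that of liver. Across 10358 genes the log2 fold changes of both tissues had a Pearson r of 0.765, above the 0.5 set for a selection of the same RNAs, which could follow from labelling in both tissues or from the pull-down itself, and the test does not tell these apart. Of these genes 2594 were higher in both where independence gives 1219, and 201 were called in opposite directions. Only unselected liver RNA is excluded as the cause. The 148 genes over 100 CPM in liver and under 1 CPM in kidney input allow a share up to 0.0277%. This gives 10% of the excess in 0 of the 3992 genes raised in kidney pull-down. A smaller carry-over is left undecided, as over 11 hepatocyte genes under 1 CPM in kidney input, the median log2 ratio of pull-down to input was 0.00161, and of the 148 genes 65 were higher and 73 lower.

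Liver mRNA input LFD 1 stood apart, and without it the count between diets went from 1328 to 5582. Kap was raised as given above, and 9 of 14 kidney genes were highest in this library. An excess above 0 was found in 11, in proportion to the kidney level at a median ratio of 0.891 of that of Kap. The log2 ratios had an interquartile range of 0.536 over the 11, under the limit of 1, but 1.85 over all 14 with the genes lacking an excess ranked lowest, so kidney RNA in the library is neither shown nor excluded. Kidney RNA as the cause of its raised genes is excluded at the share found, since it accounts for 10% of the excess in 1.65% of 121 genes. A swap with a library of another kind is excluded, as its mean correlation with liver inputs was 0.933, higher by 0.103 than with any other kind. It held 17 counts of Cyp3a13 where the other 5 held 296 to 719, and neither a swap among liver inputs nor another genotype was tested.

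Splits of the libraries into groups of the same sizes were refitted. Pull-down against input used a plain 2-group design, so real counts differ from the main test's. Of more than 100 splits 100 were drawn, after draws of 30 to 100 had been seen. No other split reached the real count, a share under 0.05 in the design refitted if libraries are interchangeable. Real and highest other counts were 6872 and 2163 in liver mRNA and 7538 and 2604 in kidney mRNA. In small RNA they were 3899 and 3524 in liver, 4582 and 112 in VsWAT and 4510 and 706 in GAS. Plasma gave 55 and 1 with all 35 splits, where leaving out 1 library still gave 0 genes in the main test. Liver minus kidney gave 884 and 385 and VsWAT minus GAS 1990 and 214. Here a number's input and pull-down formed a block, though only GAS met the pairing rule, and the main test gave 1723 and 1522. The diet effect in VsWAT minus GAS total RNA gave 212 and 31. The 10 splits of 3 against 3 are too few for a share under 0.05. Real and highest other counts were 1328 and 0 in liver mRNA input, 1571 and 0 in its pull-down and 6 and 0 in liver small RNA input. GAS small RNA pull-down gave 65 and 6, GAS total RNA 108 and 16 and VsWAT total RNA 24 and 8. The liver mRNA interaction gave 365 and 0, keeping input and pull-down of a number together. This was set after the first real split differed from the main test. Most other splits of liver mRNA input part near-identical libraries, so its 0 tells little. In 3 sets 2 of the 10 splits reached the real count: VsWAT small RNA input (17 and 34), its pull-down (11 and 58) and GAS small RNA input (14 and 15). The 58 calls point to a structure of the samples, which was not tested. For the interaction in GAS and in VsWAT small RNA all 10 splits gave 0 genes by edgeR, as did the real one, with 415 and 458 at an unadjusted p under 0.05 and 14 and 2 by DESeq2.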

How the results depend on the processing

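Of 1299 counts and summary values computed under alternatives, 1100 stayed within 1.5 times the count or within 1 SD between replicates, and 199 moved. Of the values of named genes, 569 of 636 kept their side of the threshold with DESeq2, 629 of 636 with DESeq2-type size factors, 549 of 636 with no filter, and 544 of 635 with the replicate number as a block (72 lost a call). In the sets they apply to, 193 kept it and 67 lost a call with near-identical libraries summed. Not tallied are runs without libraries picked by Gm42418, Alb or mitochondrial mRNA, which leave some groups with 1 library. With a dispersion from all 4 groups 178 kept their side, 16 lost a call and 4 gained one. Total-count scaling gave 253, 13 and 9. With 1 library left out 5669 kept it, 606 lost a call and 103 gained one, and 4 called values changed sign, all with total-count scaling. Alternatives chosen after the data were seen are named above. Counts between diets rest on at most 3 against 3 libraries, so the spread is read from few. A gene that did not pass is not shown to be unchanged. Below, brackets after a name give the main analysis, sRNA is small RNA, and causes of changes were not tested.

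With the DESeq2 test the calls were between diets 111 (GAS sRNA pull-down, 65), 455 (GAS total RNA, 108), 144 (kidney mRNA input, 0), 55 (liver sRNA input, 6), 36 (liver sRNA pull-down, 5), 70 (VsWAT sRNA input, 17), 79 (VsWAT sRNA pull-down, 11) and 196 (VsWAT total RNA, 24), for pull-down over input 73 (plasma sRNA, 33), for the diet by pull-down interaction 14 (GAS sRNA, 0), 104 (kidney mRNA, 0), 745 (liver mRNA, 365) and 2 (VsWAT sRNA, 0) and for the difference in diet effect 1138 (liver mRNA minus kidney input, 124) and 832 (VsWAT minus GAS total RNA, 212). With DESeq2-type size factors 20 plasma genes passed for pull-down over input and with total-count scaling 74, in place of 33. Total-count scaling turned Alb to 0.018, Ambp to 0.122 and Apoh to 0.123 in liver sRNA and Ttn to 0.034 in GAS sRNA, all negative in the main analysis. With no filter on low counts they were between diets 58 (GAS sRNA input, 14), 245 (GAS sRNA pull-down, 65), 377 (GAS total RNA, 108), 1536 (kidney mRNA input, 0), 10 (kidney mRNA pull-down, 0), 140 (liver sRNA input, 6), 91 (liver sRNA pull-down, 5), 1 (plasma sRNA input, 0), 202 (VsWAT sRNA input, 17), 151 (VsWAT sRNA pull-down, 11) and 621 (VsWAT total RNA, 24), for the diet by pull-down interaction 24 (GAS sRNA, 0), 480 (kidney mRNA, 0), 615 (liver mRNA, 365) and 27 (VsWAT sRNA, 0) and for the difference in diet effect 1611 (liver mRNA minus kidney input, 124) and 1185 (VsWAT minus GAS total RNA, 212). With the dispersion of all 4 groups of a tissue the counts were between diets 6 (GAS sRNA input, 14), 112 (GAS sRNA pull-down, 65), 2439 (liver mRNA input, 1328), 674 (liver mRNA pull-down, 1571), 20 (liver sRNA input, 6), 6 (VsWAT sRNA input, 17) and 45 (VsWAT sRNA pull-down, 11).

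With near-identical libraries summed, which leaves fewer libraries, edgeR called between diets 0 (liver mRNA input, 1328) and 6 (VsWAT sRNA input, 17), for the diet by pull-down interaction 0 (liver mRNA, 365) and for the difference in diet effect 6 (liver mRNA minus kidney input, 124). Without kidney inputs HFD 1 and LFD 1 it called between diets 6722 (kidney mRNA input, 0), for the diet by pull-down interaction 1420 (kidney mRNA, 0) and for the difference in diet effect 1226 (liver mRNA minus kidney input, 124), without total RNA libraries with over 3% of Gm42418 between diets 33 (GAS total RNA, 108) and 966 (VsWAT total RNA, 24) and for the difference in diet effect 0 (VsWAT minus GAS total RNA, 212), and without VsWAT replicates with over 300 CPM of Alb in input between diets 87 (VsWAT sRNA input, 17) and 6 (VsWAT sRNA pull-down, 11), for pull-down over input 1587 (VsWAT sRNA, 4975) and for the difference in enrichment 541 (VsWAT minus GAS, 1522). Leaving out 1 library at a time gave between diets 0 to 24 (GAS sRNA input, 14), 17 to 64 (GAS sRNA pull-down, 65), 1 to 140 (GAS total RNA, 108), 0 to 1647 (kidney mRNA input, 0), 0 to 463 (kidney mRNA pull-down, 0), 48 to 5582 (liver mRNA input, 1328), 0 to 13 (liver sRNA input, 6), 1 to 33 (liver sRNA pull-down, 5), 0 to 78 (plasma sRNA input, 0), 0 to 2 (plasma sRNA pull-down, 0), 5 to 68 (VsWAT sRNA input, 17), 0 to 15 (VsWAT sRNA pull-down, 11) and 4 to 81 (VsWAT total RNA, 24), for pull-down over input 0 to 360 (plasma sRNA, 33), for the difference in enrichment 1148 to 2628 (liver minus kidney, 1723), for the diet by pull-down interaction 0 to 1421 (kidney mRNA, 0), 14 to 3054 (liver mRNA, 365) and 0 to 1 (VsWAT sRNA, 0) and for the difference in diet effect 13 to 2527 (liver mRNA minus kidney input, 124) and 5 to 772 (VsWAT minus GAS total RNA, 212).

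Where replicate numbers pair all libraries compared, the replicate block changed no count by over 1.5 times. Elsewhere all or some libraries share only a number (liver mRNA pull-downs are paired between diets, and the inputs set against them are not), and the block gave between diets 56 (GAS total RNA, 108), 28 (liver mRNA input, 1328), 87 (liver sRNA pull-down, 5) and 62 (VsWAT total RNA, 24), for the difference in enrichment 1046 (liver minus kidney, 1723), for the diet by pull-down interaction 0 (liver mRNA, 365) and 2 (VsWAT sRNA, 0) and for the difference in diet effect 3 (liver mRNA minus kidney input, 124) and 99 (VsWAT minus GAS total RNA, 212). The crossed block in plasma input called 0 genes, as did the main test by edgeR (8 at an unadjusted p under 0.05, 0 by DESeq2). In VsWAT sRNA every input correlated best with the pull-down of its own number (0.085 to 0.414), a hint from the data and not from the design.

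Camera with an estimated correlation called 0 (liver mRNA minus kidney mRNA, 1), 0 (diet in GAS total RNA, 9), 0 (diet in liver mRNA input, 6), 0 (diet in VsWAT total RNA, 13), 1 (pull-down of liver mRNA, 8) and 6 (pull-down of VsWAT sRNA, 13) lists, and fry, which asks whether a list's genes move one way, 2 (liver mRNA minus kidney mRNA, 1), 1 (diet in GAS total RNA, 9), 11 (diet in liver mRNA input, 6), 1 (diet in VsWAT total RNA, 13) and 19 (pull-down of liver mRNA, 8). The calls of described lists that hold with an estimated correlation are endothelial genes in liver mRNA pull-down, macrophage, fibroblast and C/D box snoRNA lists in VsWAT pull-down, C/D box snoRNAs in GAS pull-down, fatty acid synthesis, gluconeogenesis and ER stress genes between diets in liver pull-down and adipocyte genes between diets in GAS sRNA pull-down. At a threshold of 0.01 genes higher in pull-down were shared 5.04 times as often as independent lists would in GAS and plasma (3.16 at 0.05) and 5.55 times in VsWAT and plasma (3.26), and lower genes 2.97 times in liver and plasma (0 for higher genes). Differences of class shares in percentage points, pull-down minus input, were in HFD libraries alone kidney mRNA 0.489 lncRNA (0.401), 0.0047 snoRNA (0.00235), 0.00282 snRNA (0.00201) and in liver mRNA 4.17 mito mRNA (6.33), -0.476 mito rRNA (-0.174), -3.99 protein coding (-6.4). In LFD libraries alone they were kidney mRNA 0.269 lncRNA (0.401), -0.104 mito tRNA (-0.314), -0.00117 snoRNA (0.00235), 0.000795 snRNA (0.00201), in liver mRNA 8.5 mito mRNA (6.33), 0.127 mito rRNA (-0.174), -8.81 protein coding (-6.4) and in liver sRNA 0.18 pseudogene (0.133). Without the most abundant gene of each library they were GAS sRNA -0.529 lncRNA (-0.147), -2.32 miRNA (-1.72), -13 mito rRNA (-20.7), 12 protein coding (16.1), -0.104 rRNA (-0.0701), -3.99 snoRNA (-2.98), -1.12 snRNA (-0.834), in plasma sRNA -0.895 miRNA (0.448), -20.1 rRNA (-8.59), -0.226 snoRNA (0.0336), -0.208 snRNA (0.0493), in VsWAT sRNA -1.52 miRNA (-1.27), -3.24 snoRNA (-2.73), -0.865 snRNA (-0.722), in kidney mRNA 0.414 mito mRNA (4.93), -0.414 protein coding (-4.99) and in liver mRNA 4.11 mito mRNA (6.33), -4.16 protein coding (-6.4).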

Other observations

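Cyp3a13 was counted at low levels beyond liver and kidney, with group means of up to 7.08 CPM of all assigned counts in VsWAT small RNA, 1.53 in plasma, 0.453 in GAS small RNA and 0.418 in total RNA. In plasma, Cyp3a59 had 133 counts in pull-down HFD 1 and 0 in the other 7 libraries.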
